A study of Mus musculus with 4 samples.

How the data were processed

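RNA was sequenced from 4 samples of mouse splenic T cells reactive to gp100, a protein of pigment cells. The cells came from Pmel mice, which carry a transgenic T cell receptor for a gp100 peptide. Per the labels, they were stimulated with the peptide at 1 µg/ml and with IL-2 at 100 U/ml for 72 h, and TruSeq mRNA libraries were made. 2 libraries were labelled wild-type control and 2 were labelled SphK1 −/−. The labels do not say whether libraries of 1 genotype came from separate animals, so every p-value measures only the spread between these samples, which may be technical.

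The deposited values were raw counts per gene, as whole numbers in 4 columns. The submitters' processing notes name cutadapt 1.11, TopHat2 2.0.13, HTSeq 0.6.1p1, DESeq2 1.14.1 and build GRCm38. The role of each tool, the annotation, the strand setting and the treatment of reads that fit several places were not given in the sources used here. The table held 23419 entries, of which 22672 carried a gene name. A further 27 carried a calendar date in place of a name and took 0.261% to 0.312% of the counts of each library. The remaining 720 had no name and no value in either library labelled knockout, and held 1.13% and 1.17% of the counts of the control libraries. Entries without a gene name were left out.

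Total counts were 44277592 and 46449606 in the control libraries and 50538355 and 53640611 in the libraries labelled knockout. A floor of 3 counts corresponded to between 0.0598 and 0.0639 CPM (counts scaled to library size by the cpm function of edgeR). For a gene at 0 in both libraries of a group, the fold was computed against 3 counts in each of these libraries and is given as a lower bound. For a group total of 1 to 3 counts, the ratio is given with its exact 95% counting interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

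Genes were compared between genotypes with edgeR 4.0.16 in R 4.3.3 (TMM normalisation, filterByExpr with a minimum count of 10, quasi-likelihood F test, Benjamini-Hochberg adjustment, threshold 0.05). The filter left 12758 named genes. Log2 fold changes are libraries labelled knockout over control. Their standard error (SE) was computed from the F statistic, as the absolute log2 fold change divided by the square root of F. CPM values use the TMM-scaled library sizes. DESeq2 1.42.0 and limma 3.58.1 were run as alternatives. The test, its threshold, the 33 gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

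After the first results, the change of a gene was seen to depend on how much of its sequence it shares with other genes. For every gene of GENCODE mouse release M21, the share of its 30-base words that also occur in another annotated gene, not overlapping it, was computed, with the share of its exonic bases that another gene overlaps on either strand. Symbols matched the annotation directly for 21711 named genes and through a synonym for 606, while 355 were not matched. Genes with at most 5% shared words and at most 10% overlap are called single-copy genes here, and 9034 of them passed the filter in a fit of their own. This set was defined after the dependence had been seen. The first set looked at allowed at most 2% of both, and the wider limits were chosen after it, so both are given among the alternatives, with sets that allowed 0% of both or used 40-base words. Copies outside annotated genes were not searched, because only transcript sequences were used. Of the 12758 genes tested, 12650 could be placed on the annotation.

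The 33 lists covered the S1P pathway, central memory and naive genes, effector genes, inhibitory receptors and exhaustion, regulatory T cells, helper cytokines and regulators, homing and chemokine receptors, survival and apoptosis, FoxO-associated genes, the interferon response, and immediate early and stress genes. Metabolic and growth lists covered fatty acid oxidation and lipolysis, lipid synthesis with uptake and storage, cholesterol synthesis, glycolysis, nuclear and mitochondrially encoded oxidative phosphorylation, mitochondrial biogenesis and dynamics, the tricarboxylic acid cycle, proliferation, amino acid and endoplasmic reticulum stress, hypoxia and cytoplasmic ribosomal proteins. Marker lists covered B cells, macrophages and monocytes, dendritic cells with MHC class II, neutrophils with mast cells and basophils, natural killer cells, helper T cells, cytotoxic T cell identity and erythroid cells. Sex-linked genes and T cell receptor variable segments made up the rest. Lists with at least 5 tested members were tested with camera (limma) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera asks whether the members of a list rank differently from all other genes. It was repeated with a correlation estimated from the data. That form rests on the spread between libraries, with only 2 per group, so even a list without correlation can lose its call. A call lost there is therefore no measure of correlation within a list. Fry was also run, which asks only whether the members move on balance in 1 direction and compares them with no other gene. Members past the threshold were counted over all genes tested and adjusted over the list alone. Markers of other cell types were also summed per library over the single-copy members.

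Named genes were chosen by rule. The rule took Sphk1, Sphk2 and 18 genes fixed in advance. It added the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold, with a mean of at least 5 CPM in the higher group and no overlap between the groups, leaving out predicted genes, genes named only by an identifier, sex-linked genes and segments of antigen receptors. It also took up to 4 members of each list past the threshold, or the member with the highest expression where none passed. The parts based on the threshold were repeated in the fit of single-copy genes, after the data had been seen. 9 neighbours of Sphk1 were named after their values were seen, though the rule also named St6galnac1, and Mxra7 in the fit of single-copy genes. 3 genes that the rule named are not reported here.

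The share of called genes within 10 Mb of Sphk1 was compared with the share elsewhere by Fisher's exact test, two-sided. Alternatives covered the normalisation, the low-count filter, the test, the threshold, the set of genes, the correlation within lists, the replicate number as a block and the removal of each library in turn, which leaves 1 library in a group that is assumed to vary like the other group. The edgeR fit and camera with the preset correlation were tested on simulated data with known changes. Genes were simulated independently and without any dependence on shared sequence. The choice of single-copy genes, fry, the estimated correlation, the preset correlation itself and the test around Sphk1 were therefore not checked. Over all named genes, 36.4%, 63.6% and 92.3% of genes changed by 1.5-fold, 2-fold and 4-fold were recovered, and 10.7% of the calls were false. Over single-copy genes, 30.3%, 75.8% and 96.9% were recovered, and 6.29% of the calls were false. A list with every member raised 1.5-fold was called in both, and 1 of 27 other lists was called among single-copy genes.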

Results

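Gene counts came from 4 RNA sequencing libraries of activated mouse T cells that carry a receptor for gp100. 2 libraries were labelled wild-type control and 2 were labelled SphK1 −/−, that is, deficient in sphingosine kinase 1. This enzyme phosphorylates sphingosine to the lipid mediator sphingosine-1-phosphate (S1P). The series title places the comparison in a study of S1P, T cell metabolism and tumour control, so the comparison asks which transcripts differ when the kinase is missing. Depth was 44277592 and 46449606 counts in the control libraries and 50538355 and 53640611 in the libraries labelled knockout. Because Sphk1 itself ran against the labels, the groups are named by their labels throughout.

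Sphk1 transcripts were barely detected in the control libraries and were higher in both libraries labelled knockout. The gene lies on chromosome 11 from 116530925 to 116536674 (GRCm38). Control 1 and control 2 held 2 and 4 reads, or 0.0426 and 0.0797 CPM. Knockout 1 and knockout 2 held 35 and 18 reads, or 0.745 and 0.371 CPM. Group means were 0.0612 ± 0.0263 CPM (SD, n = 2) under the control label and 0.558 ± 0.264 CPM (SD, n = 2) under the knockout label. The log2 fold change was 3.12 ± 0.66 (SE), with an adjusted p of 0.0233 in edgeR. Which exons the knockout allele lacks was not given in the sources used here, and a floor of 3 counts lay at 0.0598 to 0.0639 CPM. The call was lost without control 1 (adjusted p = 0.162), without control 2 (0.0746), without knockout 1 (0.239), with the DESeq2 Wald test (0.0717) and among single-copy genes (0.131).

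No other member of the S1P pathway list passed the threshold. Sphk2, the other sphingosine kinase, stood at 45.5 ± 1.3 CPM (SD, n = 2) in the control libraries and 43.5 ± 1.47 CPM (SD, n = 2) in the libraries labelled knockout, a log2 fold change of −0.066 (adjusted p = 0.848). S1pr1, the S1P receptor that guides T cells out of lymphoid tissue, had a log2 fold change of −0.40 (adjusted p = 0.446). Without control 1 it fell by 0.68 (adjusted p = 0.0144), and without control 2 the change was 0.0066. Of 28 tested members of the S1P list, Sphk1 alone passed the threshold, over all genes and adjusted over the list alone. The camera test pointed down (adjusted p = 0.556), as did the median log2 fold change of −0.031, while the mean was 0.046. Among single-copy genes the test pointed up (adjusted p = 0.718).

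Over the whole table, 861 of 12758 tested genes passed the threshold, 765 higher and 96 lower in the libraries labelled knockout. Transcripts of cytoplasmic ribosomal proteins stood out: 70 of 80 tested members rose (71 adjusted over the list alone), with a median log2 fold change of 3.34. They took 11.3% and 10.5% of the counts in the libraries labelled knockout, against 2.91% and 2.79% in the control libraries. Rpl19, for example, was at 3.38 ± 0.0175 CPM in the control libraries and at 1778 ± 58.1 CPM in the libraries labelled knockout (SD, n = 2 each). Rpl23a (log2 fold change 9.23), Rps28 (8.87), Rpl5 (8.43), Rpsa (8.37), Rpl21 (8.31) and Rpl24 (8.04) rose as steeply. Camera gave the list an adjusted p of 9.74e-71, with an adjusted p of 0.575 with an estimated correlation and 0.0158 in fry. Without control 2, 230 genes were lower in place of 96. With library totals alone, the median log2 fold change of all genes moved from −0.021 to −0.26, and 652 genes were higher and 1432 lower.

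The rise followed the sequence that a gene shares with other genes. Among genes with at most 10% exonic overlap, 0.979% of the 5003 that shared no 30-base word rose, against 20% of the 471 that shared 10% to 20% and 57.9% of the 107 that shared over 70%. The median log2 fold change climbed from −0.057 to 1.90 between the first and the last of these classes. Falls were more frequent with overlap, although 2.8% of the genes sharing over 70% also fell, against 0.52% of those that shared no word. Among genes sharing at most 5% of their words, 3.85% of the 494 with over 30% of their exons under another gene fell, against 0.466% of the 6655 with no overlap. Genes with copies or overlaps are therefore reported as uncertain.

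**Figure D1:**
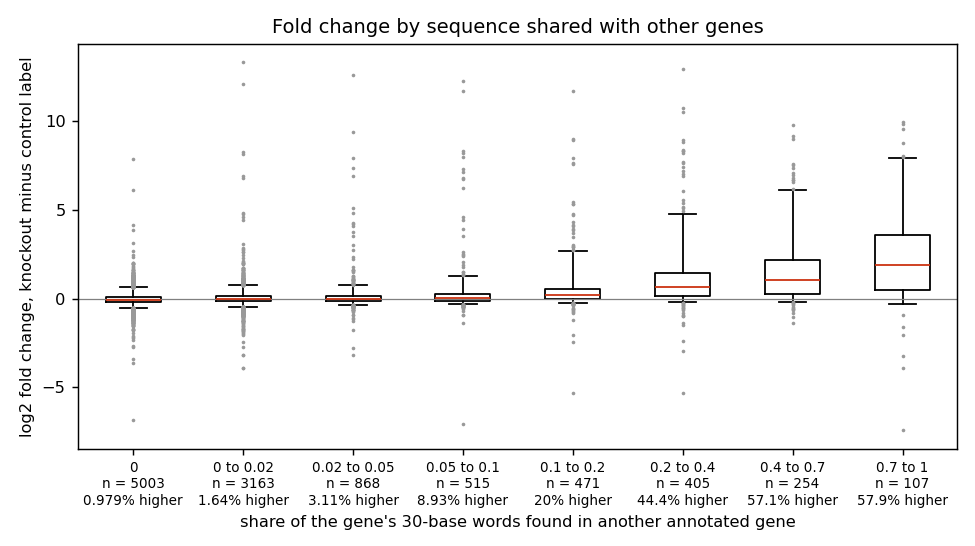
Log2 fold change of each tested gene with at most 10% exonic overlap (vertical axis), by the share of its 30-base words found in another annotated gene (horizontal axis). Boxes give the quartiles with the median in red, whiskers run from the 5th to the 95th percentile, dots are single genes beyond them, and the share of genes that rose climbs from 0.979% to 57.9%.

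Many of the most extreme values sat on genes of this kind. Mrgpra6, with 24.1% shared words, held 0 and 1 reads in the control libraries and 5444 and 4236 in the libraries labelled knockout, a ratio of 9839 (95% counting interval 1770 to 389000). Olfr613 (at least 210-fold higher) and Zfp488 (at least 144-fold higher) had 0 reads in both control libraries. In the opposite direction, 8 named genes had 0 reads in both libraries labelled knockout. They were Evi2b (at least 1470-fold lower), Pisd-ps3 (1310-fold), Vamp7 (654-fold), Trpc2 (493-fold), Dhrsx (277-fold), Tmlhe (212-fold), Akap2 (160-fold) and Mir142 (111-fold), each as a lower bound. Other genes cover 98.6% of the exons of Evi2b, 84.4% of Akap2 and 100% of Trpc2 and Mir142, while the shared words of Pisd-ps3, Vamp7, Dhrsx and Tmlhe were not computed. Vamp7 and Tmlhe have 0% overlap and lie on a scaffold outside the chromosomes, so their falls do not follow overlap. Whether both genotypes were counted against the same annotation was not given in the sources used here. The 720 entries with no value in either library labelled knockout argue against the same set of entries for both groups. Log2 fold changes were −6.57 for Adnp, −6.09 for Dpm1 and −5.61 for Pla2g4b, with 82.1%, 12% and 66.5% of their exons under other genes.

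Among single-copy genes 67 of 9034 passed the threshold, 58 higher and 9 lower, and all 67 were among the 861. Of the 861, 172 were single-copy and 689 were not. In the fit over all genes the gradient went on within this class, since 0.979%, 1.64% and 3.11% of genes sharing 0, up to 2% and 2% to 5% of their words rose, and 13 of the 27 risers in the last rose by 8-fold or more. With 0% allowed, 4 of 3729 genes passed the threshold, 2 higher and 2 lower. A difference in counting between the groups would coincide with the genotype labels, so it cannot be told apart from genotype in single-copy genes either. Both chains of the interleukin-18 receptor, Il18rap (log2 fold change 2.07 ± 0.18, adjusted p = 0.00247) and Il18r1 (1.62 ± 0.15, 0.00384), rose in the libraries labelled knockout. So did Rora, a nuclear receptor of type 17 and innate lymphocytes (2.92 ± 0.27, 0.00384), and Ccr2, a chemokine receptor (1.30 ± 0.19, 0.0312). The activation-induced transcription factors Nr4a3 (2.02 ± 0.27, 0.0223) and Egr3 (1.80 ± 0.26, 0.0267) rose as well. Il17a, the cytokine of type 17 cells, had 1 and 0 reads in the control libraries and 58 and 28 in the libraries labelled knockout, a ratio of 87.4 (95% counting interval 15.3 to 3490; adjusted p = 0.031). Itga1, an integrin chain of tissue-resident T cells, rose by 2.86 ± 0.43 (0.031). Ccr2, Il17a and Itga1 lost their calls without knockout 1 (adjusted p = 0.104, 0.0927 and 0.123), Itga1 also without control 1 (0.059), Nr4a3 with robust fitting (0.183) and Egr3 with limma-voom (0.0645).

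Other single-copy genes that rose included Ube2s, a ubiquitin-conjugating enzyme of mitosis, at 16.8 ± 2.29 CPM in the control libraries and 246.9 ± 2.6 CPM in the libraries labelled knockout (SD, n = 2 each; log2 fold change 3.92, adjusted p = 1.64e-05). Prnp, the prion protein gene, rose by 2.50 ± 0.12 (8.86e-05), and Cpeb4, a translation regulator, by 2.37 ± 0.17 (0.000801). Dsg2 rose by 2.77 (0.014) and Gas7 by 2.18 (0.0224). Adarb2 had 0 reads in both control libraries and was at least 188-fold higher, while Brat1, Olfr856-ps1 and Prex2, each with at most 10 control reads, had log2 fold changes of 8.33, 8.21 and 6.85. The fold changes of these 4 genes resemble those of genes with copies, and copies outside the annotation were not searched. The same limit covers Ube2s, whose log2 fold change of 3.92 lies above the median of 3.34 of the ribosomal protein list. Gas7 lost its call without knockout 1 (0.0619).

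Falls among single-copy genes were fewer. Bmf, which encodes a pro-apoptotic protein that binds BCL-2, fell by 1.40 ± 0.19 on the log2 scale (adjusted p = 0.0223), from 15.8 ± 0.0364 CPM to 5.83 ± 0.726 CPM (SD, n = 2 each). Clk2, a splicing kinase, fell by 2.32 (0.000149), Lars2, the mitochondrial leucyl-tRNA synthetase, fell by 1.60 (0.00334), and Alcam, an adhesion molecule that binds CD6, fell by 1.02 (0.0253). Stk39, a kinase of ion transport, fell by 0.70 (0.0399). Clhc1 had a log2 fold change of −6.80 (1.87e-05), which is as uncertain as the extreme rises, with 7.22% of its exons under another gene. Bmf lost its call without knockout 2 (0.0678), Alcam without knockout 1 (0.104) or 2 (0.0518), and Stk39 without control 1 (0.0562), knockout 1 (0.22) or knockout 2 (0.128) and in the set at 2% (0.0575). The number of single-copy calls rose to 675 without control 2 and dropped to 42 without knockout 1.

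**Figure D2:**
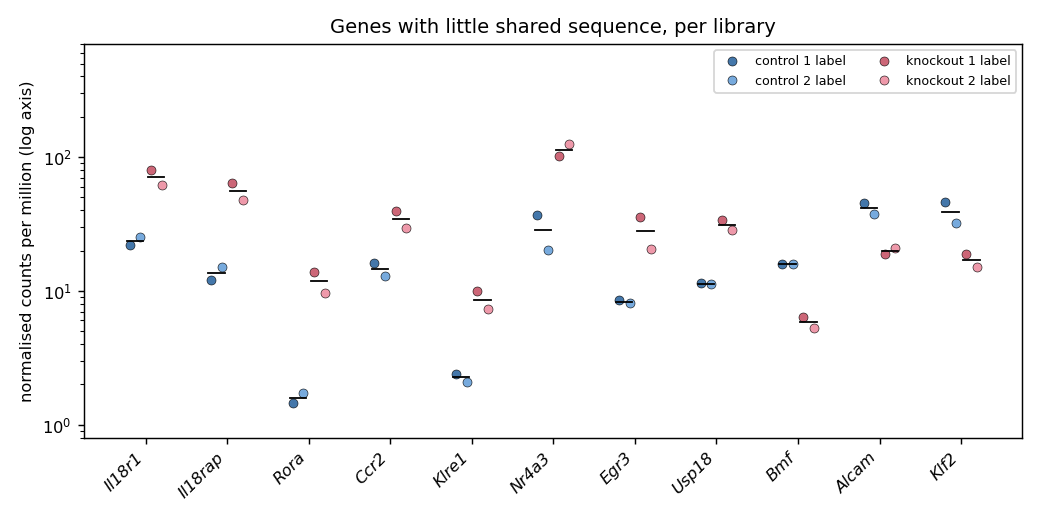
Normalised CPM (log axis) of 11 single-copy genes in each library, with horizontal lines at the mean of each group of 2. For Il18r1, Il18rap, Rora, Ccr2, Klre1, Nr4a3, Egr3 and Usp18 both libraries labelled knockout lie above both control libraries, and for Bmf, Alcam and Klf2 they lie below; Klf2 had an adjusted p of 0.0592 among single-copy genes.

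Genes of cholesterol and lipid synthesis were mostly lower in the libraries labelled knockout, by small amounts. In the cholesterol list, 15 of 17 single-copy members had a negative log2 fold change (median −0.27, camera adjusted p = 1.21e-05; adjusted p = 0.503 with an estimated correlation). Adjusted over the list alone 6 of the 17 fell, whereas over all single-copy genes the lowest adjusted p was that of Pmvk, phosphomevalonate kinase (0.08). In the list of lipid synthesis, uptake and storage, 19 of 21 single-copy members were negative (median −0.18, adjusted p = 0.000119; adjusted p = 0.503 with an estimated correlation), and 3 fell adjusted over the list alone. Fads2, a fatty acid desaturase, fell by 0.72 ± 0.13 over all genes (adjusted p = 0.00939; 0.0843 among single-copy genes), and Vldlr, a lipoprotein receptor, fell by 1.53 ± 0.32 (0.0211; 0.16). Fry gave both lists an adjusted p of 0.0895 among single-copy genes. Natural killer and macrophage markers, given below with their low levels, were higher in both libraries labelled knockout. Cytotoxic T cell identity markers summed to 0.953 and 1.01 times the control mean there. Fads2 lost its call without knockout 1 (0.0665), and Vldlr with robust fitting (0.122) and limma-voom (0.0693), while its fall shrank to −0.84 without control 1 (0.046).

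Over all genes, both lists also held risers, which share words with other genes. The cholesterol list had 24 tested members, 2 higher and 5 lower (3 and 11 adjusted over the list alone), with a median of −0.32, a mean of −0.022 and a camera adjusted p of 0.00325 (0.624 with an estimated correlation, and 0.746 with an upward sign in fry). Its 2 risers were Idi1 (log2 fold change 4.79) and Fdps (1.28), with 32.1% and 64.3% shared words. Among its fallers Pmvk fell by 0.72, and Acat2, with 45.4% shared words, had a log2 fold change of −0.57. Acat2 lost its call without control 2 (adjusted p = 0.0515), knockout 1 (0.0854) or knockout 2 (0.051), and the list call was lost with library totals alone (0.0557). The lipid list had 28 tested members, 2 higher and 4 lower (2 and 6 adjusted over the list alone), a median of −0.21 and an adjusted p of 0.00222 (0.575 with an estimated correlation, 0.0451 in fry). Its risers were Acaca (1.48) and Fabp5 (0.77), with 57.1% and 33.4% shared words. Fabp5 lost its call without control 2 (0.0642) or knockout 2 (0.0732) and with library totals alone (0.0509). Pparg, the regulator of lipid storage, had a log2 fold change of −1.36 ± 0.40 (0.102), and fell by 1.74 without control 2 (0.0279) and by 1.60 with library totals alone (0.0418).

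**Figure D3:**
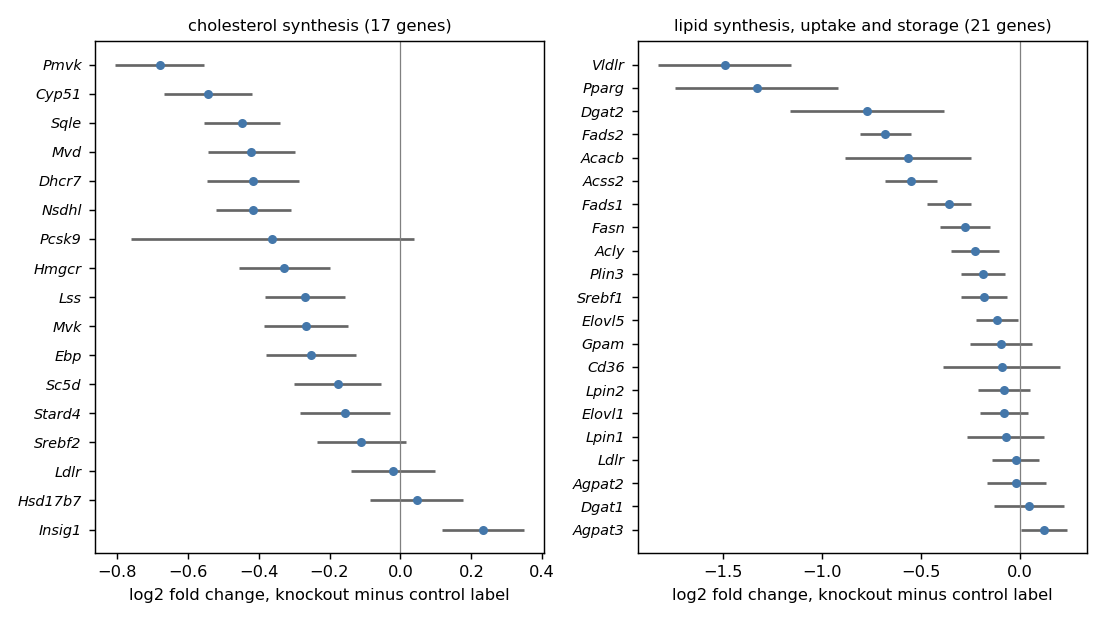
Log2 fold change (horizontal axis, libraries labelled knockout over control) of the single-copy members of the cholesterol synthesis list (17 genes) and of the list of lipid synthesis, uptake and storage (21 genes). Bars are 1 standard error, computed from the F statistic. 15 of 17 and 19 of 21 genes lie below 0.

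Interferon response genes were higher. Of 36 tested members 32 had a positive log2 fold change (median 0.29, camera adjusted p = 3.56e-05; adjusted p = 0.575 with an estimated correlation), and 5 rose (6 adjusted over the list alone). Among single-copy genes 21 of 22 were positive (median 0.33, adjusted p = 4.53e-07; adjusted p = 0.503 with an estimated correlation), 1 rose over all single-copy genes and 4 adjusted over the list alone. That gene was Usp18, a brake on interferon signalling, which went from 11.3 ± 0.192 CPM to 31.1 ± 3.51 CPM (SD, n = 2 each; log2 fold change 1.5, adjusted p = 0.00637). Mx1 (0.99, adjusted p = 0.018), Gbp6 (0.89, 0.00927) and Zbp1 (0.52, 0.0188) also rose over all genes, where Gbp6 and Mx1 share 84.2% and 9.28% of their words and Zbp1 had an adjusted p of 0.0909 among single-copy genes. In fry both list calls were lost too (adjusted p = 0.0964 and 0.26). Natural killer and macrophage markers were also higher in both libraries labelled knockout (sums of 2.9 and 1.73, and of 2.46 and 1.49, times the control mean). Mx1 lost its call without knockout 1 (0.0685) and with library totals alone (0.0512), and Zbp1 without control 2 (0.0546), knockout 1 (0.119) or knockout 2 (0.057) and with library totals alone (0.0762).

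The list of helper cytokines and regulators was also higher. Among single-copy genes 19 of 23 members were positive (median 0.63, camera adjusted p = 9.38e-06; adjusted p = 0.803 with an estimated correlation), and 4 rose (7 adjusted over the list alone): Il18rap, Il18r1, Rora and Il17a. Over all genes 5 of 27 rose (6 adjusted over the list alone), with a median of 0.58 and an adjusted p of 0.00171 (0.875 with an estimated correlation). Fry gave adjusted p values of 0.617 among single-copy genes and 0.441 over all genes. The call over all genes was lost without control 2 (0.0822) and without knockout 1 (0.0951). Natural killer and macrophage markers, given below, moved in the same direction.

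FoxO-associated genes were lower as a list. 17 of 22 members were negative over all genes (median −0.22, camera adjusted p = 0.0072; adjusted p = 0.575 with an estimated correlation), and 3 fell, over all genes and adjusted over the list alone. Klf2, the transcription factor that drives S1pr1, went from 39.1 ± 9.64 CPM to 17.0 ± 2.67 CPM (SD, n = 2 each) and fell by 1.21 ± 0.20 (adjusted p = 0.00532). Trib2 fell by 0.61 (0.0232), and Ccng2 had a log2 fold change of −0.49 (0.0436). Among single-copy genes the list kept its sign (15 of 21 negative, median −0.19, adjusted p = 0.00618; adjusted p = 0.503 with an estimated correlation), 3 members fell adjusted over the list alone, and the lowest adjusted p was that of Klf2 (0.0592). Fry gave the list adjusted p values of 0.0964 over all genes and 0.0895 among single-copy genes. Here too, natural killer and macrophage markers were higher in both libraries labelled knockout, at the low levels given below. Cytotoxic T cell identity markers summed to 0.953 and 1.01 times the control mean. The list calls were lost without control 2 (0.0702 and 0.0776), that of Trib2 without knockout 1 (0.148) or knockout 2 (0.121), and that of Ccng2 under 7 of 17 alternatives, among them the removal of control 1 (0.185) or knockout 1 (0.352). Among single-copy genes, Trib2 and Ccng2 had adjusted p values of 0.143 and 0.262.

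The lists of memory, effector and exhaustion genes did not pass the threshold. In the central memory and naive list, 1 of 27 members rose (1 adjusted over the list alone) and 2 fell (3 adjusted over the list alone), with a median of −0.015 and a camera adjusted p of 0.539. Dapl1 rose by 0.73 (adjusted p = 0.0343), while Klf2 and the co-stimulatory receptor Cd27 (−0.49, 0.0413) fell. Dapl1 and Cd27 had adjusted p values of 0.135 and 0.254 among single-copy genes, and both lost their calls without control 1 (0.102 and 0.181) or knockout 1 (0.313 and 0.33), Cd27 also without knockout 2 (0.0509). In all, these calls were lost under 5 of 17 alternatives for Dapl1 and 7 of 17 for Cd27. Log2 fold changes were −0.17 for Ccr7 (0.639), 0.12 for Il7r (0.706), −0.018 for Tcf7 (0.976) and −0.026 for Foxo1 (0.941). Ccr7 changed sign without control 1, Tcf7 without control 2 or knockout 1, Foxo1 without control 2, and Il7r with library totals alone.

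In the effector list no member of 32 passed the threshold in edgeR, over all genes or adjusted over the list alone (camera adjusted p = 0.431, upward). The list call appeared without control 1 (0.0417) or knockout 2 (0.0453), and the direction turned without control 2 or knockout 1. The log2 fold changes were −0.15 for Gzmb (adjusted p = 0.798), 0.22 for Tbx21 (0.636), −0.14 for Il2ra (0.787) and 0.17 for Ifng (0.868). Gzmb turned positive without control 1, Il2ra without control 1 or knockout 1, and Tbx21 turned negative without knockout 1 and with library totals alone. Ifng was at 112.8 and 46.2 CPM in the control libraries and rose by 0.99 without control 1 (0.00993), but had a log2 fold change of −0.33 without control 2. The inhibitory receptor and exhaustion list had 20 members, of which 1, Nr4a3, rose (2 adjusted over the list alone; camera adjusted p = 0.792, median −0.017, mean 0.16). Pdcd1, which encodes PD-1, had a log2 fold change of −0.25 (0.72), fell by 0.72 without knockout 2 (0.0266) and was at 0.11 without knockout 1. Regulatory T cell genes (17 members, adjusted p = 0.829) held no call, and Foxp3 had a log2 fold change of 0.38 (0.763).

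Homing receptors gave 3 risers of 26 (5 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.436), among them Ccr2 and Itga1. The survival list (30 members, adjusted p = 0.47) held 1 call, the fall of Bmf, while Bcl2 had a log2 fold change of 0.055 (0.885). Its sign turned with library totals alone. In the immediate early list 1 of 23 members, Egr3, rose, against a negative median of −0.20 (camera adjusted p = 0.121), and the list call appeared without control 2 (0.0179) or knockout 1 (0.00185).

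The risers named here for energy metabolism share 12.8% or more of their words with other genes. In glycolysis 5 of 28 members rose (6 higher and 1 lower adjusted over the list alone), among them Pgam1 (log2 fold change 5.41), Pgk1 (4.59), Gapdh (3.49) and Eno1 (3.36), which share 42.2% to 80% of their words. The median was −0.047, the mean 0.55 and the camera test pointed up (adjusted p = 0.431), whereas among single-copy genes it pointed down (0.109). Slc2a1, the glucose transporter, had a log2 fold change of −0.35 (0.401) and Hk2, a hexokinase, −0.17 (0.589). Slc2a1 fell by 0.58 without control 2 (0.0319) and was at −0.033 without control 1, and Hk2 fell by 0.40 with library totals alone (0.042). In nuclear oxidative phosphorylation 15 of 75 members rose (17 adjusted over the list alone), led by Atp5g2 (7.72), Cycs (6.92), Ndufab1 (5.36) and Atp5l (4.71), with 12.8% to 87.8% shared words. The camera adjusted p of 0.00497 became 0.875 with an estimated correlation and 0.0964 in fry, and the test pointed down among single-copy genes (0.335). The call was lost without control 2 (0.436), without knockout 2 (0.0893) and with library totals alone (0.0557).

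The fatty acid oxidation list did not pass the threshold (38 members, 1 higher and 1 lower, the same counts adjusted over the list alone; camera adjusted p = 0.829, downward, with a mean of 0.065). Hadhb rose by 3.01, with 63.1% shared words, and Acsl3 fell by 0.57 (adjusted p = 0.0279; 0.174 among single-copy genes; 0.118 without control 1 and 0.215 without knockout 1). Cpt1a, the carnitine palmitoyltransferase that limits the pathway, had a log2 fold change of 0.030 (0.947), which turned negative without control 1 or knockout 2, with library totals alone and with upper-quartile scaling. Pnpla2, the triglyceride lipase, had one of −0.025 (0.941), which turned positive without control 1. The tricarboxylic acid cycle (23 members, adjusted p = 0.47, median −0.064, mean 0.00024) had 2 risers, Suclg2 and Pdhb, with 25.5% and 42.6% shared words. Mitochondrial biogenesis and dynamics (22 members, adjusted p = 0.895, median −0.025, mean 0.18) had 2, Tfb2m and Bnip3, with 44.3% and 61.9%. Bnip3 was also the 1 riser of the hypoxia list (20 members, adjusted p = 0.312, downward), whose call appeared without control 2 (0.00577). Pdhb (0.54, 0.0263) lost its call without control 2 (0.0758), without knockout 2 (0.167) and with library totals alone (0.0783).

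Proliferation genes were slightly lower among single-copy genes: 17 of 19 members were negative (median −0.13, camera adjusted p = 0.0102). The adjusted p was 0.803 with an estimated correlation and 0.7 in fry, and the call was lost without control 1 (0.115) or knockout 1 (0.663). Over all genes the list had an adjusted p of 0.303 (median −0.14, mean 0.012), and 2 of 34 members, Ccnb1 (1.82) and Pcna (1.25), rose, with 46.1% and 38.4% shared words. The list of amino acid and endoplasmic reticulum stress was lower over all genes (23 of 29 negative, median −0.24, adjusted p = 0.00497) and among single-copy genes (15 of 23, median −0.24, 0.00257; 2 lower adjusted over the list alone). With an estimated correlation these became 0.875 and 0.803, and in fry 0.68 and 0.712. Beside this list and the proliferation list, natural killer and macrophage markers, given below, were higher in both libraries labelled knockout. Cytotoxic T cell identity markers summed to 0.953 and 1.01 times the control mean. Cth fell by 1.08 (0.0107, and 0.1 among single-copy genes). Trib3 had a log2 fold change of −1.0 (0.0304, and 0.201 among single-copy genes), while Phgdh rose by 1.81, with 74.8% shared words. The list calls were lost without control 1 (0.369 and 0.496), and over all genes also without knockout 1 (0.0522) and with library totals alone (0.0557). Cth lost its call without control 1 (0.0529) or knockout 1 (0.0735), and Trib3 without control 1 (−0.52, 0.065), with a stricter filter (0.0551), robust fitting (0.123) and limma-voom (0.0509).

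Markers of natural killer cells and macrophages were higher in both libraries labelled knockout. All 14 tested natural killer markers had a positive log2 fold change (median 1.1, camera adjusted p = 7e-07; adjusted p = 0.696 with an estimated correlation), and 3 rose (10 adjusted over the list alone): Klre1 (1.93, adjusted p = 0.00133), Klra7 (1.80, 0.00094) and Klra1 (2.06, 0.00969). Klra7 and Klra1 share 25.6% and 8.66% of their words. Only 4 of the 14 are single-copy genes, too few for a list test in that set, and all 4 were positive (median 1.21). The list call over all genes thus rests largely on genes reported here as uncertain. Summed over the 4 single-copy markers, knockout 1 and knockout 2 were at 2.9 and 1.73 times the control mean. These sums, which include Klre1, were 13.65 and 12.38 CPM in the control libraries, and 37.67 and 22.53 CPM in knockout 1 and knockout 2. Macrophage sums were 52.9 and 57.7 CPM, and 136 and 82.7 CPM, in the same order. They include Ccr2, at 16.0 and 12.9 CPM, and 39.6 and 29.5 CPM, so neither sum is independent of the risers named above. Cytotoxic T cell identity markers summed to between 5302 and 5768 CPM in every library. For macrophages 2 of 10 rose, Ccr2 and Cd68 (1.08, 0.0478), with an adjusted p of 0.00421 (0.575 with an estimated correlation) and sums of 2.46 and 1.49 times the control mean. Among single-copy genes the macrophage list had an adjusted p of 0.000172 (0.659 with an estimated correlation), with 1 of 5 members higher (5 adjusted over the list alone). In fry the adjusted p values were 0.194 for natural killer cells, and 0.194 and 0.36 for macrophages. Without knockout 1 the call of Klra1 was lost (0.0829), as was that of Klre1 among single-copy genes (0.0795). The call of Cd68 was lost under 10 of 17 alternatives, among them the removal of control 1 (0.187) or knockout 1 (0.361) and single-copy genes (0.195).

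Markers of B cells and dendritic cells separated the libraries labelled knockout from each other. Summed B cell markers stood at 1.84 times the control mean in knockout 1 and 0.903 times in knockout 2. Dendritic and MHC class II markers stood at 1.55 and 0.76 times, and those of neutrophils, mast cells and basophils at 1.35 and 0.766 times. The B cell list had 2 risers of 15, Ebf1 (1.73, adjusted p = 0.013) and Cd79a (1.48, 0.0236), and a camera adjusted p of 0.0707, or 0.0161 among single-copy genes (0.803 with an estimated correlation). Without knockout 1 the direction turned, with adjusted p values of 0.501 and 0.416. The dendritic list had 2 risers of 17 (4 adjusted over the list alone), Ccl22 (1.77, 0.0188) and Flt3 (1.94, 0.0332), and a camera adjusted p of 0.193 over all genes or 0.0347 among single-copy genes (0.803 with an estimated correlation), and its direction also turned without knockout 1 (0.243 and 0.61). The rise of Cd79a shrank to 0.77 without knockout 1. All 4 of these genes lost their calls without control 1, and Ccl22 (0.0527), Flt3 (0.379) and Ebf1 (0.0521) without knockout 1. Among single-copy genes the calls of Ccl22 (0.121), Flt3 (0.165) and Ebf1 (0.0909) were lost as well. In all, calls were lost under 6 of 16 alternatives for Cd79a, with control 2 removed among them (0.0761), under 7 of 16 for Flt3, again with control 2 removed among them (0.0643), under 5 of 17 for Ccl22 and under 3 of 17 for Ebf1. Knockout 1 thus stands apart in markers of these cells.

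The remaining marker lists held no list call. Adjusted p values were 0.303 for neutrophils, mast cells and basophils (12 members, no call over all genes; Kit at 0.043, 0.959), 0.874 for helper T cells (9 members, 1 riser, Il17a; median −0.053, mean 0.63) and 0.0707 for cytotoxic T cell identity (15 members, no call; Thy1 at 0.19, 0.709). Without knockout 2 the cytotoxic list passed downward (0.0489). Helper T cell sums were 0.94 and 0.955 times the control mean, and cytotoxic sums 0.953 and 1.01 times. Erythroid markers (6 members, adjusted p = 0.556) stood at 1.93 and 1.1 times, with 1 riser, Car2 (1.47, 0.0286), which lost its call under 7 of 17 alternatives, among them the removal of control 1 (0.12), control 2 (0.0706) or knockout 1 (0.21) and single-copy genes (0.16). Sex-linked genes had 4 tested members, too few for a list test, and 1 riser, Eif2s3x (4.36), with 36.5% shared words. Mitochondrially encoded genes and T cell receptor variable segments were not among the named entries.

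Some genes near Sphk1 on chromosome 11 rose steeply, whereas the nearest tested genes on either side, Ube2o (log2 fold change 0.23, adjusted p = 0.396) and Prpsap1 (−0.061, 0.857), did not pass the threshold. BC018473 held 1 and 0 reads in the control libraries and 5423 and 7346 in the libraries labelled knockout, a ratio of 12980 (95% counting interval 2330 to 513000). Mxra7 went from 0.379 ± 0.0843 CPM to 9.44 ± 0.366 CPM (SD, n = 2 each; log2 fold change 4.67 among single-copy genes, adjusted p = 0.000357). St6galnac1, with 43.8% shared words, had a ratio of 985.9 (interval 337 to 4780) and St6galnac2 a log2 fold change of 6.56. Cygb, at 1 and 1 against 22 and 17 reads, had a ratio of 19.8 (interval 5.13 to 169) and an adjusted p of 0.00909, which was lost without control 1 (0.0825), control 2 (0.0705) or knockout 1 (0.0627), with the DESeq2 Wald test (0.0625) and among single-copy genes (0.0573). In the opposite direction, Fads6 had 19 and 31 reads in the control libraries and 1 and 2 in the libraries labelled knockout (adjusted p = 0.0085; 0.0612 among single-copy genes), and Mettl23, which is not a single-copy gene, had a log2 fold change of −0.75 (adjusted p = 0.0238). Neither was repeated under the other alternatives. All 9 neighbours named here were chosen after their values were seen, though the rule also named St6galnac1, and Mxra7 in the fit of single-copy genes. The annotation used here gave no position for St6galnac2. Within 10 Mb of Sphk1, 18 of 183 tested genes were called (16 higher and 2 lower), against 832 of 12466 elsewhere (Fisher's exact test, two-sided, p = 0.0999).

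**Figure D4:**
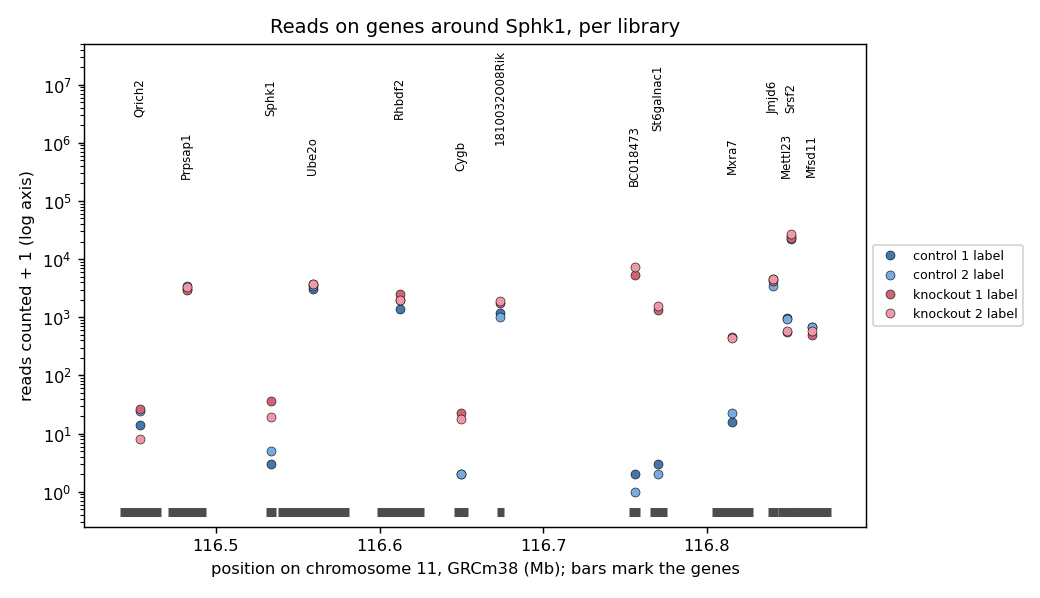
Reads counted per gene plus 1 (log axis) in each library, by position on chromosome 11 (GRCm38, Mb), for genes around Sphk1, with bars marking the extent of each gene. Sphk1, Cygb, St6galnac1, Mxra7 and BC018473 have more reads in both libraries labelled knockout than in both control libraries. Some other genes shown do so as well, by smaller amounts. Reads are not scaled to library size.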

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

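The set of single-copy genes and every repeat within it, the sets at 2% and 0% or by 40-base words, the fit without the legacy option and the thinned counts were chosen after the results had been seen. For named genes over all genes, 1562 values under alternatives kept direction and side of the threshold, 101 kept direction but lost the call, 7 gained one and 35 changed sign. For lists over all genes the numbers were 368, 37, 15 and 25. For called single-copy genes, with Klf2, they were 427, 15, 5 and 0, and for called single-copy lists 116, 40, 0 and 2. Left out of these counts, after their sign changes had been seen, were 17 single-copy lists and 36 named single-copy genes that did not pass the threshold. Of their 271 and 599 values under alternatives, 17 (in 10 lists) and 13 (in 10 genes) changed sign, and 15 and 68 passed the threshold.

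Among all genes, 575 to 1120 were called with the other scalings, filters, models and tests and without each library in turn, except for 2084 with library totals alone. The single-copy set gave 67 and the set at 0% gave 4, with fewer genes tested (9034 and 3729). Within single-copy genes 67 calls became 125 with the replicate number as a block (103 higher, 22 lower), 178 with DESeq2 (138 higher, 40 lower), 25 with glmTreat at 1.5-fold, 26 at an adjusted p under 0.01, 35 in the set at 2% (6740 tested, all 35 shared), 4 in the set at 0% and 75 by 40-base words (67 shared). Without 1 library they ranged from 42 (knockout 1) to 675 (control 2). The cause was not tested, except that smaller sets test fewer genes and the stricter limits ask for more.

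The log2 fold change of Sphk1 was 3.19 with DESeq2 and 3.16 among single-copy genes, neither past the threshold, and ranged from 2.54 (without knockout 1) to 3.64 (without control 2). Around Sphk1, the region test gave an odds ratio under 1 in the window of 20 Mb among single-copy genes (Fisher's exact p = 1).

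With library totals alone the log2 fold changes became −0.18 for Bcl2, −0.21 for Cpt1a, −0.058 for Ifng, −0.12 for Il7r, −0.19 for Kit, −0.015 for Tbx21 and −0.056 for Thy1; this scaling lowers every gene by about the same amount. With limma-voom they became −0.032 for Kit and 0.0097 for Tcf7, with the block −0.028 for Kit and 0.0081 for Tcf7, and with upper-quartile scaling −0.0070 for Cpt1a. Among single-copy genes they became 0.014 for Foxo1, 0.014 for Pnpla2 and 0.025 for Tcf7, and with a stricter filter 0.0031 for Foxo1, 0.0035 for Pnpla2 and 0.011 for Tcf7. The cause was not tested.

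Leaving out 1 library, which leaves a lone sample assumed to vary like the other group, gave log2 fold changes from −0.37 to 0.060 for Il2ra, −0.50 to 0.43 for Kit, −0.72 to 0.11 for Pdcd1, −0.034 to 0.44 for Tbx21, −0.036 to 0.00040 for Pnpla2, −0.30 to 0.017 for Ccr7, −0.11 to 0.23 for Cpt1a and −0.062 to 0.049 for Foxo1. For Gzmb they ran from −0.38 to 0.17, for Ifng from −0.33 to 0.99, for S1pr1 from −0.68 to 0.0066, for Tcf7 from −0.25 to 0.30 and for Thy1 from −0.015 to 0.47. For Pdcd1 and Il2ra the ends were set by knockout 2 and knockout 1, and for Ifng, S1pr1, Gzmb, Tcf7, Ccr7 and Thy1 by the controls.

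Against 10 lists past the threshold over all genes, 9 to 14 passed under the other scalings, filters and removals, 0 with an estimated correlation (with the block also 0) and 2 in fry. Against 10 lists among single-copy genes, 8 to 13 passed, 0 with an estimated correlation (with the block also 0) and 0 in fry. At an unadjusted p under 0.05 the estimated correlation gave 1 and 2 lists, and fry 6 and 4. Some lists lost their calls although their estimate lay below the preset 0.01. Interferon response over all genes (−0.0040) went from an unadjusted p of 3.56e-06 to 0.0328 in camera. Cholesterol synthesis among single-copy genes (−0.028) went from 1.35e-06 to 0.0349. Correlation within these lists cannot account for the loss. Other called lists had higher estimates, up to 0.583 and 0.916, and for them this form cannot decide. Lists of other cell types past the threshold numbered 2 over all genes, 4 with library totals alone, 0 with an estimated correlation with or without the block, 0 in fry, and 2 to 5 without 1 library (5 without knockout 2). Among single-copy genes there were 3, 1 with a stricter filter, 0 with an estimated correlation with or without the block, 0 in fry, and 1 to 4 without 1 library (1 without control 2 or knockout 1, 4 without knockout 2). With the replicate block the immediate early list passed the threshold (adjusted p = 0.021). The causes of these differences were not otherwise tested.

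Directions of lists that turned, with the adjusted p there, were S1P (0.925), cholesterol synthesis (0.746) and fatty acid oxidation (0.469) in fry, mitochondrial biogenesis with library totals alone (0.708) and upper-quartile scaling (0.992), inhibitory receptors with no filter (0.994) and helper T cells with a stricter filter (0.541). Among single-copy genes S1P (0.718), glycolysis (0.109), mitochondrial biogenesis (0.609) and oxidative phosphorylation (0.335) turned. The cause was not tested.

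Without 1 library, lists with a turned direction had adjusted p values from 3.53e-08 to 0.501 (B cells; 3.32e-10 to 0.416 among single-copy genes), 0.000174 to 0.621 (dendritic cells; 2.42e-05 to 0.61), 0.0417 to 0.978 (effector), 0.385 to 0.868 (fatty acid oxidation), 0.582 to 0.846 (helper T cells), 0.707 to 0.958 (mitochondrial biogenesis) and 0.0146 to 0.846 (proliferation). The ranges were 0.369 to 0.978 for regulatory T cells, 0.0701 to 0.757 for the tricarboxylic acid cycle, 0.00577 to 0.475 for hypoxia, 0.385 to 0.999 for inhibitory receptors and 0.182 to 0.985 for glycolysis. For B cells and dendritic cells the direction turned without knockout 1.

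Libraries of 1 group differed by more than counting error: the chi-square per gene was 47.95 between the control libraries and 31.36 between the libraries labelled knockout. Libraries with the same replicate number did not deviate together (correlation −0.037 over all genes and −0.0365 over single-copy genes), so the replicate block is given here only. Depth limits genes near the floor of 3 counts, such as Sphk1 in the control libraries, while thinning all libraries to the smallest total left 847 calls.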

Other observations

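The tests in this part were chosen after the results had been seen, except for the test over all genes in windows around Sphk1. What the thinning of the counts would show was set down before it was run.

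Genes with copies were higher in the libraries labelled knockout. Outside the ribosomal list, 50% of the genes that share over 40% of their words rose (195 of 390), against 0.904% of the 5973 that share none, so a candidate explanation is that reads matching several genes were counted for 1 genotype and left out for the other. A real rise of all ribosomal protein transcripts, as steep as in those with copies, has values against it. The 5 ribosomal genes sharing at most 10% had a median log2 fold change of 0.064 (range −0.039 to 2.35, SD 1.06). For the other 75 it was 3.41, and 68 rose. A smaller or partial real rise stays open. Of the 5 genes 2 rose, against 0.979% to 8.93% of genes with at most 10% overlap in the sharing classes up to 10%. So few genes cannot decide it. As to the greater depth of the libraries labelled knockout, 847 genes were called after thinning to the smallest total. Totals ran only from 44277592 to 53640611 counts and the fit scales to library size. Thinning could therefore hardly change the number of calls, and no conclusion is drawn from it. A change in expression of single genes with copies stays open as untested, and Rpl19, Gapdh and genes like them cannot be read either way from counts alone.

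Sphk1 and some genes near it (BC018473, Mxra7, St6galnac1, St6galnac2 and Cygb, chosen for their values) were higher under the knockout label, while its nearest tested neighbours did not pass the threshold. An altered locus that changes transcription nearby stays open. Within 10 Mb the share of called genes did not pass the test over all genes (Fisher's exact test, two-sided, p = 0.0999), and windows of 5 and 20 Mb gave exact p values of 0.0707 and 0.459. These tests cannot decide it, because calls inside and outside the windows include genes with copies. The windows are also wide, whereas Cygb, BC018473, St6galnac1 and Mxra7 start 108.9 to 266.4 kb from the end of Sphk1. A long flanking stretch from another strain stays open as well, because 2 calls among single-copy genes within 10 Mb are too few (Fisher's exact test, two-sided, p = 0.284; odds ratio 1.94, interval 0.228 to 7.43). Exchanged labels stay open too: the highest Sphk1 value under the knockout label was 0.745 CPM, and without the deleted exons no value separates residual from normal transcript. A difference in counting between the groups stays open as well. St6galnac1 shares 43.8% of its words, and BC018473, at 1 and 0 against 5423 and 7346 reads, rose as steeply as genes with copies. Sphk1 and Cygb share 0% and Mxra7 shares 1.74%, but copies outside the annotation were not searched. The effect of the missing kinase itself was not tested apart from these.

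Il18r1, Il18rap, Rora, Ccr2 and Klre1 were higher in both libraries labelled knockout, at 2.74 to 8.71 times the control mean in knockout 1 and 2.04 to 6.08 times in knockout 2. More B cells are argued against for knockout 2 only by the sum of the single-copy B cell markers, at 0.903 times the control mean. Single B cell genes went the other way there: Ebf1 was at 6.71 CPM (control mean 2.93) and Cd79a at 37.9 CPM (22.2). Macrophage markers, whose sum includes Ccr2, stood at 2.46 and 1.49 times the control mean, and whether these cells contribute was not tested. Natural killer cells may contribute: the 3 single-copy markers other than Klre1 summed to 11.24 and 10.28 CPM in the control libraries and 27.76 and 15.28 CPM under the knockout label, at least 1.42 times the control mean in each. A change within the T cells that follows the genotype stays open as untested.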
